A study of Mus musculus with 26 samples.

How the data were processed

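Double positive (DP) cells, the thymocyte stage that carries both CD4 and CD8 on its surface, were sorted from thymus, mediastinal adipose tissue and aortic arch of female C57BL/6J mice aged 8 weeks. Each pool joined the tissue of 5 mice. There were 4 pools per tissue and 1 to 3 libraries per pool, which gave 9 libraries from thymus, 8 from mediastinal adipose tissue and 9 from aortic arch. Per the labels' protocols, arch and adipose tissue were enzymatically digested (digestion is not stated for thymus), viable cells positive for CD4 and CD8b and negative for the T-cell receptor were sorted in lots of 400, and the lysate of 200 cells went into each library. Complementary DNA of polyadenylated RNA was amplified for 18 cycles and read as single ends of 50 bp. FastQC 0.11.5, STAR 2.6.0c and the genome build GRCm38 are named in the submitters' processing notes; the counting tool and the annotation are not given in the sources used here.

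The deposited table holds 1 normalised signal per gene and pool for 13765 genes and 12 columns, so the libraries of a pool had already been combined. The values are not whole. In each column every value is a whole multiple of its smallest value, the step that 1 read is worth, and all 120369 values above 0 (100%) came out whole within 0.01 after division by that step. The steps match size factors of the kind DESeq2 computes from the recovered reads, and the smallest gene total was 10 recovered reads. Values are called normalised read counts below. Mitochondrial genome transcripts and T-cell receptor constant genes, including Trac, were not analysed here.

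Recovered reads per column ranged from 11577253 to 34599519. Since the deposited unit is a signal and not raw counts, the edgeR test planned for the 3 comparisons was replaced as the main test by limma 3.58.1 with an intensity trend on log2(normalised read count + 20), run in R 4.3.3. The recovered reads did allow the planned edgeR test with TMM scaling. It was run as an alternative with the filter below and called fewer genes than limma in each comparison. The pseudocount of 20 equals 0.983 CPM, the read count scaled to a common total, in the median column, or 10.5 to 35.3 reads. Fold changes are on that scale, where the pseudocount lowers the change of weakly expressed genes. They average log2 values over pools and can exceed the ratio of means where a pool stands apart from others near 0. Nr4a2 and Slc39a6 in arch against thymus were such genes. Genes with at least 100 in at least 4 columns (4.91 CPM in the median column) were tested, which left 9106 genes holding 98.1% to 99.6% of each column's total. All 12 columns entered a single fit with tissue as the only term, each comparison was a contrast, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The pool of mice was the replicate (4 per tissue). Errors of log2 values are standard errors (SE) from this fit, and errors of normalised counts are standard deviations (SD) over 4 pools.

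For a gene without reads in a tissue the fold is a lower bound against 3 reads in each of its 4 pools; for a gene with 1 to 3 reads the ratio of means is given with an exact 95% Poisson interval. Reads were amplified and carry no molecular identifiers, so intervals and floors cover counting error only.

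The comparisons, most of the alternatives, the naming rule and 35 gene lists (22 of cell programs, 13 of cell types outside the sort gate) were fixed before the data were examined. The naming rule took, per comparison and direction, the 8 called genes with the largest log2 change, a mean of at least 10 CPM in the higher tissue and pool values that did not overlap, leaving out predicted genes, unnamed clones, pseudogenes and receptor segments. It added up to 4 members per list with the smallest p and sort and identity genes, among them Cd4, Cd8a, Cd8b1, Rag1, Rag2, Ptcra and Dntt. Some genes that the rule names are not reported here. Lists with at least 5 tested members (20 of them) were tested with limma's camera at a preset correlation of 0.01, adjusted over 60 tests (20 lists in 3 comparisons), and again with an estimated correlation. None of the 20 list calls held with the estimated correlation (limma's camera: 0 in each comparison), against 9, 8 and 3 calls at the preset value. limma's fry, which tests whether a list's genes move on balance one way, made 9, 6 and 1 calls of partly other lists. It added effector and memory genes in arch against thymus and glucocorticoid response genes in adipose tissue against thymus. It did not call ribosomal protein genes in arch against thymus (adjusted p = 0.0513), cholesterol, S phase and oxidative phosphorylation genes in adipose tissue against thymus (0.0628, 0.282 and 0.325), or immediate early and ribosomal protein genes in arch against adipose tissue (0.214 and 0.0768). Marker lists of other cell types were summed as CPM per pool and compared by exact two-sided permutation tests over 70 assignments of 8 pools, whose smallest p is 0.0286. Of 183 markers, 4 also stood in another list and 115 were measured. Of the measured markers, 17 had a thymus mean of at least 100.

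Recovered reads were tested with edgeR 4.0.16 and DESeq2 1.42.0 as alternatives; other alternatives changed the scaling, the pseudocount, the filter, the threshold, a covariate, the samples in the fit, the depth and the set of pools. Coordinates are those of the RefSeq annotation of GRCm38, to which 13681 of 13765 gene names were matched (12298 by symbol, the others through synonyms). Reads of genes with near-identical copies, such as Hspa1a and Hspa1b, Ftl1 and other genes with many processed pseudogenes, and ribosomal protein genes, could be divided differently by another counting method, and their values are uncertain to that extent.

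The testing steps were tested on simulated counts with 200 changed genes. For aortic arch against thymus (8870 genes), 1.59% of genes changed 2-fold, 16.4% of those changed 4-fold and 56.7% of those changed 16-fold were called, and 4 of 49 calls were false. For mediastinal adipose tissue against thymus (8920 genes) the shares were 0%, 29% and 63.3%, with 6 of 62 calls false. For arch against adipose tissue (8909 genes) they were 3.17%, 27% and 60.9%, with 7 of 65 calls false. Changes of 2-fold were thus mostly under the detection limit of 4 pools against 4. In all 3 comparisons the share of false calls was above the threshold set for the adjusted p. For a list of unchanged genes camera gave an unadjusted p of 0.498 in arch against thymus and 0.653 in adipose tissue against thymus. In arch against adipose tissue it gave 0.0362, so a camera p of that size arose there without a change.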

Results

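Transcriptomes of CD4 and CD8 double positive cells without a surface T-cell receptor were measured at 3 sites: the thymus, where such cells arise, the adipose tissue of the mediastinum around it, and the arch of the aorta. The series sets DP cells residing in these tissues side by side. The 26 libraries fell into 4 pools of 5 mice per tissue, and the deposited values give 1 normalised read count per gene and pool. Pools, not libraries, are the replicates, so n = 4 per tissue throughout.

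Recovered reads numbered 34599519, 26605699, 13473516 and 22986138 in thymus pools 1 to 4 and 33540294, 14279190, 29843835 and 26916064 in adipose pools 1 to 4. In arch pools 1 to 4 they numbered 26093045, 11577253, 26551456 and 14291241. Thymus pool 3 (6736758 reads per library), arch pool 2 (5788626) and arch pool 4 (7145620) had the fewest reads per library and are called the 3 shallow columns below. Per column, adipose pool 2, with 1 library, had slightly fewer reads than arch pool 4. Between 9091 and 11894 genes had at least 1 read. The number of detected genes was 9936 ± 583 in thymus, 10433 ± 1110 in adipose tissue and 9723 ± 555 in arch (SD, n = 4). The 50 most abundant genes took 16.5% ± 0.344 of the normalised total in arch, 13.7% ± 0.536 in thymus and 13.6% ± 1.05 in adipose tissue (SD, n = 4). Arch exceeded each of the others with an exact permutation p of 0.0286, the smallest 4 pools against 4 can give, which became 0.0858 after adjustment over 12 comparisons of library measures.

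Pools of different tissues were less alike than pools of the same tissue for both comparisons with thymus. The mean distance (1 minus Spearman's correlation over the 9106 tested genes) between arch and thymus pools exceeded the mean within those tissues by 0.0760, and that between adipose and thymus pools by 0.0499 (one-sided exact permutation p = 0.0286 each, 1 of 35 splits). Between arch and adipose pools the excess was 0.0135 and 2 of 35 splits gave as much (exact p = 0.0571), so these pools were not separated at the 0.05 level. Without adipose pool 2 that excess was -0.00012 and without adipose pool 4 it was -0.00423. On the first principal component of log2 values (22.2% of the variance) thymus pools lay between -66.2 and -53.78, adipose pools between -15.42 and -1.833, and arch pools 1 and 3 at 16.82 and 12.09. Arch pools 2 and 4 lay apart at 95.94 and 138.6.

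Transcripts of cells outside the sort gate were uneven between pools of the same tissue. Fibroblast markers summed to 7015 CPM in arch pool 4 and to 132.1 to 359.7 CPM in the other arch pools; Dcn, which encodes the matrix proteoglycan decorin, reached a normalised count of 65756 in that pool. Smooth muscle markers summed to 1977 CPM in arch pool 2, and macrophage and monocyte markers to 2349 CPM in arch pool 2 and 949.4 CPM in arch pool 4, against 248.3 to 594.0 CPM in thymus. Adipose pool 1 held 1815 CPM of B cell markers, with Cd74 at 19754, and 223.3 CPM of adipocyte markers. The exact permutation test of marker sums between tissues gave a lowest adjusted p of 0.836 over 13 lists and 3 comparisons. Its smallest p is 0.0286, so a list could pass only if most of these comparisons reached it, and a miss does not show equal sums. Several sums were led by a gene that thymus also expresses, such as Gsn among fibroblast and Gzma among NK and innate lymphoid cell markers. Without the most abundant marker of each list, fibroblast markers summed to 1258 ± 2340 CPM in arch and 1.645 ± 1.63 in thymus (SD, n = 4). NK and innate lymphoid cell markers, then led by Rora, summed to 29.7 ± 13.2 CPM in arch, 34.45 ± 20.6 in adipose tissue and 0.0258 ± 0.035 in thymus (SD, n = 4). All pools of the first tissue lay above all thymus pools in these 3 comparisons (exact permutation p = 0.0286 each, the smallest possible; adjusted p = 0.371). With all markers the lowest unadjusted p were 0.0571 for thymic epithelium markers, whose sum was led by the protease gene Ctsl (893.4 CPM in arch, 558.5 in thymus), and 0.0571 for erythroid markers (33.1 CPM in arch, 7.65 in adipose tissue). Of 10 erythroid markers 3 were measured, and the arch sum was Car2 alone. Without Car2 it was 0 CPM in arch and 2.618 CPM in adipose tissue, the other way round. With TMM library sizes thymic epithelium markers gave an exact p of 0.0286 (937.5 against 525.2 CPM, adjusted p = 0.637). Gene by gene, limma called Ctsl higher in arch than in thymus (0.79 ± 0.23, adjusted p = 0.0473, kept in 1 of 8 fits without 1 pool). It called Rora, a marker of innate lymphoid cells without a thymus read, in adipose tissue (at least 255-fold higher, adjusted p = 0.0171, kept in 6 of 8). In arch against thymus edgeR called Rora (adjusted p = 0.0151) and Dcn (0.0375), which limma did not (0.076 and 0.1). DESeq2, run on more weakly expressed genes too, called 12 markers in arch against thymus (11 higher, 4 of them of fibroblasts, and 1 lower), 6 in adipose tissue against thymus (all higher) and 3 in arch against adipose tissue (2 higher). These genes were singled out after their values were seen. Several DESeq2 calls had log2 changes too large to be read as sizes. In arch against thymus, Mgp was at 25.1 and Lrrn4 at -24.5. Fibroblast markers without Gsn, among them the Mgp and Col6a1 that DESeq2 called in adipose tissue, summed to 258.6 CPM in adipose pool 1. In adipose pools 2 to 4 they summed to 0.2101, 0.3016 and 0.03715 CPM, so those calls rested on pool 1. Lrrn4 was at 0 CPM in thymus pools 2 and 4. Sums over arch, adipose and thymus were 287.3, 279.7 and 255.6 CPM for dendritic cell, 29.9, 12.6 and 12.1 for neutrophil, 93.6, 121.0 and 91.9 for NK and innate lymphoid cell, 110.1, 166.1 and 83.1 for endothelial and 4.69, 3.06 and 3.39 for cardiomyocyte markers. For mesothelium markers, of which only Lrrn4 was measured, they were 0, 0.00838 and 11.7 CPM.

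**Figure D1:**
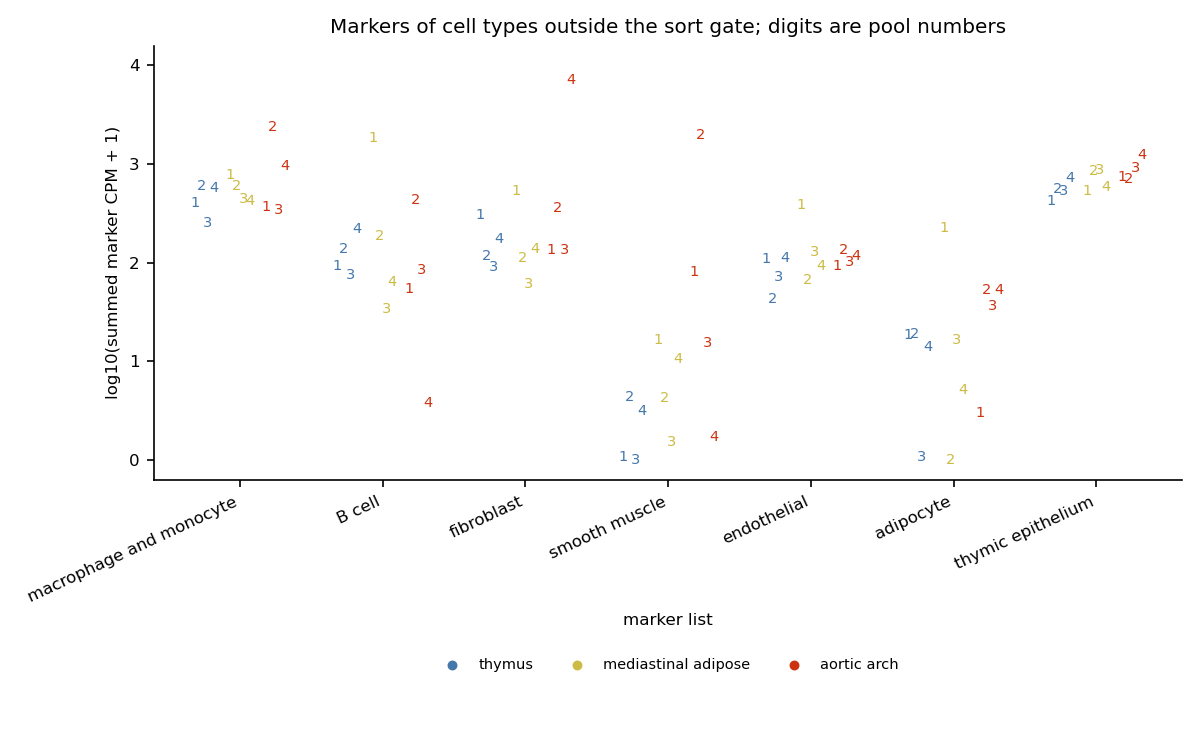
Summed CPM of 7 marker lists in each pool, shown as log10(CPM + 1) per list, with each digit giving the pool number and its colour the tissue. Arch pool 4 stands out for fibroblast markers (7015 CPM), arch pool 2 for smooth muscle (1977 CPM) and macrophage markers (2349 CPM), and adipose pool 1 for B cell markers (1815 CPM).

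DP sorts from the aortic arch had higher heat shock and immediate early transcripts and lower thymocyte transcripts than DP sorts from thymus. Hsp90aa1, a cytosolic chaperone gene (chromosome 12, 110691036 to 110696395, GRCm38), rose from a normalised count of 9619 ± 2270 to 206200 ± 34300 (SD, n = 4), a log2 change of 4.44 ± 0.30. Fosl2, a member of the AP-1 transcription factor family (chromosome 5, 32136472 to 32157840), rose from 3 reads in all thymus pools to 14375 reads in arch, a ratio of normalised means of 9330 (95% interval 3190 to 45300). Cd8b1, which encodes the CD8 chain used for the sort (chromosome 6, 71322788 to 71337492), fell by 1.47 ± 0.23. Rag2, a subunit of the receptor gene recombinase (chromosome 2, 101624712 to 101632528), fell by 3.60 ± 0.60. In all, 598 of 9106 genes were called, 363 higher and 235 lower in arch.

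Of 18 tested heat shock genes, chaperones and cochaperones induced by unfolded protein, 13 rose, 0 fell and 5 did not pass; adjusted over the list alone, 16 rose. The median log2 change was 2.16 (camera adjusted p = 4.6e-18; adjusted p = 0.0538 with an estimated correlation). Hsph1 rose by 5.80 ± 0.42, Hspe1 by 5.37 ± 0.40 and Hspd1, its mitochondrial chaperonin partner, by 3.66 ± 0.35. Hspa1a, the inducible Hsp70 gene (chromosome 17, 34969359 to 34972156), had no read in thymus and 6172 ± 2790 in arch, at least 2290-fold higher, with reads possibly shared with its near copy Hspa1b. Of 27 immediate early genes, transcribed within minutes of a stimulus, 13 rose, 0 fell and 14 did not pass (14 higher and 1 lower when adjusted over the list alone). Their median was 2.47 (camera adjusted p = 6.07e-11; adjusted p = 0.0538 with an estimated correlation), with Junb at 4.26 ± 0.43, the phosphatase gene Dusp1 at 3.49 ± 0.34 and Ier2 at 2.62 ± 0.32. In arch pools 1 and 3 the markers of other cells, without the most abundant of each list, summed to 359.6 and 227.5 CPM (183.6 to 406.2 in thymus), and the heat shock medians were 2.08 and 2.40 above the thymus mean. Fibroblast markers without Gsn were above those of all thymus pools in these pools too. In arch pools 2 and 4 the markers summed to 3220 and 5620 CPM and the medians were 2.26 and 2.37. Immediate early medians were higher in these pools (2.81 and 2.82) than in arch pools 1 and 3 (2.27 and 1.09).

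**Figure D2:**
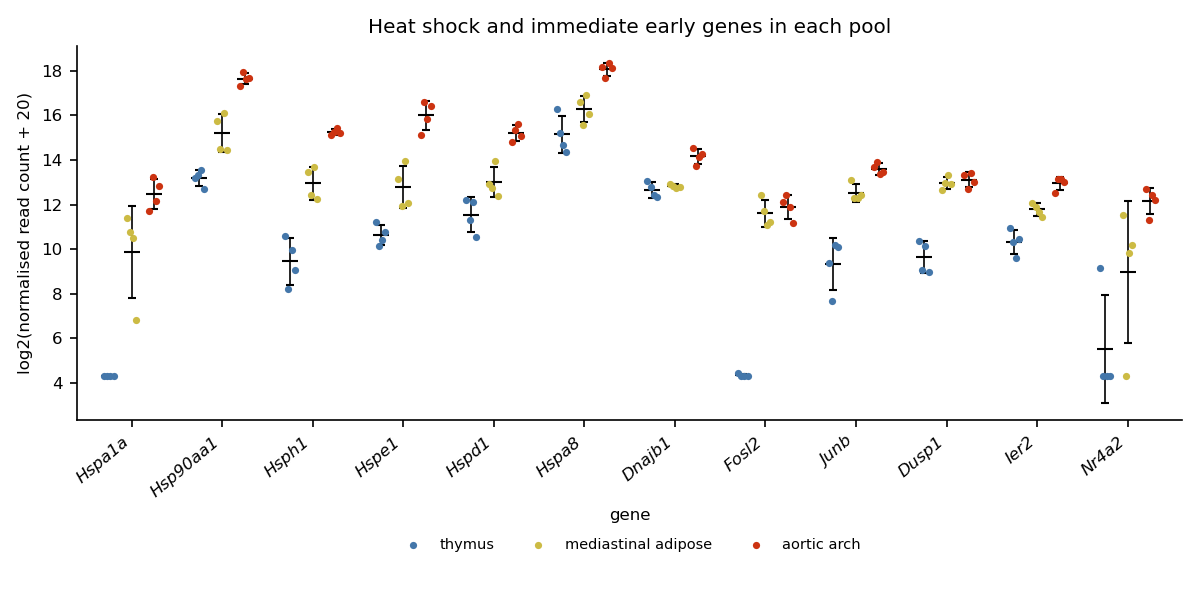
Heat shock genes (left 7) and immediate early genes (right 5) as log2(normalised read count + 20) in each pool of thymus, mediastinal adipose tissue and aortic arch; points are pools, and black bars are the mean ± SD of 4 pools. All arch pools lie above all thymus pools for every gene shown; Hsp90aa1 averaged 206200 normalised reads in arch, 42590 in adipose tissue and 9619 in thymus.

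Thymocyte identity genes were lower in arch as a group. Of 30 members, 13 fell, 1 rose and 16 did not pass; adjusted over the list alone, 22 fell and 1 rose. The median log2 change was -0.99 (camera adjusted p = 5.41e-08; adjusted p = 0.0538 with an estimated correlation), while the median of all tested genes was -0.21. Satb1, a chromatin organiser of thymocytes, fell by 1.38 ± 0.14, Tcf7, a transcription factor of the T lineage, by 0.97 ± 0.15, Cd8a by 1.08 ± 0.23, Cd4 by 1.30 ± 0.28 and Dntt, the polymerase that adds untemplated nucleotides to receptor genes, by 1.19 ± 0.20. Rag1 (-0.998 ± 0.34, adjusted p = 0.0829) and Ptcra, the pre-receptor alpha chain gene (-0.94 ± 0.50, adjusted p = 0.269), did not pass. The member that rose was Cd24a, the gene of a surface glycoprotein of immature thymocytes, by 2.56 ± 0.23. The 4 tested CD3 genes did not pass (median -0.39), with Cd247 at -0.06 ± 0.15 and Cd3e at -0.49 ± 0.20. List medians of the 4 arch pools lay between -1.10 and -0.97, in the pools with and without raised fibroblast or smooth muscle markers.

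**Figure D3:**
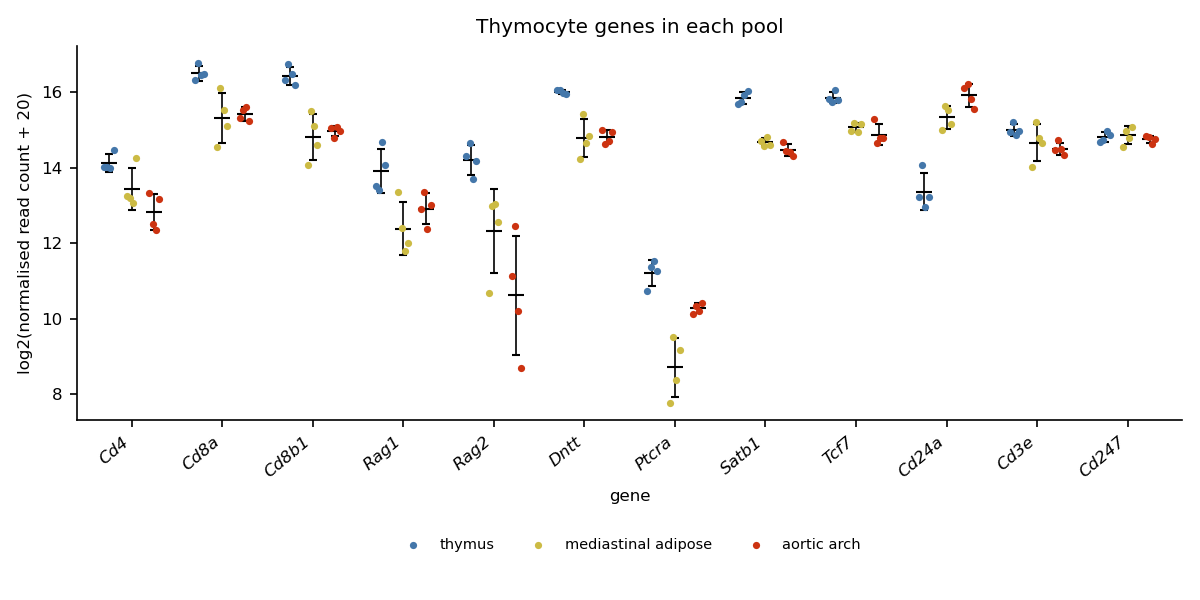
Thymocyte and CD3 genes as log2(normalised read count + 20) in each pool of thymus, mediastinal adipose tissue and aortic arch; points are pools, and black bars are the mean ± SD of 4 pools. Cd8b1 averaged 89670 normalised reads in thymus, 30740 in adipose tissue and 32240 in arch, whereas Cd24a averaged 11050, 41810 and 63070.

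Further lists that rose in arch against thymus held fewer called members. Of 22 genes of the unfolded protein and integrated stress responses, 5 rose and 0 fell, also adjusted over the list alone. Their median was 0.65 (camera adjusted p = 5.99e-05, adjusted p = 0.0538 with an estimated correlation), and Hspa5, the chaperone of the endoplasmic reticulum, rose by 1.80 ± 0.29 and Atf4 by 1.95 ± 0.37. Of 19 oxidative stress genes 6 rose and 0 fell, with 7 higher when adjusted over the list alone (median 0.44, camera adjusted p = 0.00568, adjusted p = 0.169 with an estimated correlation). Prdx6 rose by 1.79 ± 0.19 and the ferritin gene Ftl1 by 1.18 ± 0.14. Hmox1, heme oxygenase 1, went from 1 read in thymus to 8142 in arch (ratio 20800, 95% interval 3740 to 823000). Its arch mean of 2949 ± 3790 (SD, n = 4) rested on arch pool 4 (8545), without which the mean was 1084 and the ratio 7660. Of 76 ribosomal protein genes 10 rose and 0 fell, with 23 higher when adjusted over the list alone (median 0.46, camera adjusted p = 3.03e-10, adjusted p = 0.468 with an estimated correlation), and Rpl15 rose by 0.84 ± 0.15. Of 23 cholesterol biosynthesis genes 3 rose and 0 fell, with 4 higher when adjusted over the list alone (median 0.67, camera adjusted p = 0.0162, adjusted p = 0.151 with an estimated correlation). Insig1, a sterol sensor, led them at 3.56 ± 0.54. Without the 3 shallow columns (arch pools 2 and 4, thymus pool 3) the oxidative stress call was lost (camera adjusted p = 0.149), and without Insig1 the cholesterol call (0.0567).

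Of 24 genes of the p53 and apoptosis list 3 rose and 1 fell in arch, 6 and 2 when adjusted over the list alone (median 0.67, camera adjusted p = 0.0183, adjusted p = 0.21 with an estimated correlation). Bcl2l11, the gene of the death-promoting protein Bim, rose by 3.87 ± 0.40 and the cell cycle inhibitor Cdkn1a by 5.33 ± 1.00, while Trp53inp1 fell by 1.17 ± 0.33. Of 16 glucocorticoid response genes 5 rose and 2 fell, 8 and 4 when adjusted over the list alone (median 0.53, camera adjusted p = 0.0353, adjusted p = 0.141 with an estimated correlation). Per1, a clock gene, rose by 6.72 ± 0.74, Rgs2 by 3.31 ± 0.39 and Tsc22d3 by 2.12 ± 0.26. The p53 call was lost without Bcl2l11 (camera adjusted p = 0.0632) and without arch pool 1 (0.061). The glucocorticoid call was lost without Per1 (0.188) or the 3 shallow columns (0.0544), and was kept in 6 of 8 fits without 1 pool, the highest adjusted p being 0.054 without thymus pool 4.

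The other lists did not pass camera in arch against thymus, though single members did. Among 5 early double-negative thymocyte genes (camera adjusted p = 0.615, median -0.86, mean 0.37) 1 rose, also adjusted over the list alone: Hes1, a Notch target, by 5.18 ± 1.10. Among 21 post-selection genes (0.95, median -0.14 with an upward camera direction) 3 rose and 1 fell, 3 and 5 when adjusted over the list alone. Klf2, a regulator of thymic egress, rose by 5.46 ± 0.89. Among 16 effector and memory genes (0.216, but a fry adjusted p of 0.0373; median -0.08, mean 0.68) 2 rose, 3 with 1 lower when adjusted over the list alone, and Id2 was at 2.44 ± 0.55. The inhibitor gene Tnfaip3 rose by 1.98 ± 0.32 as the called member of 17 NF-kB targets (0.0864, also 1 adjusted over the list alone). By limma 0 of 20 type I interferon genes passed, also adjusted over the list alone (0.277, median -1.25), with 3 at an unadjusted p under 0.05 and 0 by edgeR and DESeq2.

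Among 23 trafficking genes (camera adjusted p = 0.355) 2 rose and 3 fell in arch, 2 and 4 when adjusted over the list alone, with Selplg, the selectin ligand gene, at 0.98 ± 0.22 and Coro1a, an actin regulator, at -1.50 ± 0.23. Among 29 fatty acid genes (0.928, median -0.29 with an upward camera direction) 2 rose and 2 fell, 5 and 3 when adjusted over the list alone. Acsl3 rose by 2.37 ± 0.40 and the lipid droplet gene Plin2 by 2.22 ± 0.40, and the mitochondrial carrier Ucp2 fell by 1.11 ± 0.21. Of 26 hypoxia and glycolysis genes (0.301) 2 rose, 3 with 1 lower when adjusted over the list alone. Of 39 S phase genes (0.122) 2 rose, 1 when adjusted over the list alone. Of 40 genes of G2 and M phase (0.615) 1 fell, 0 by limma when adjusted over the list alone. Of 75 oxidative phosphorylation genes (0.615) 1 fell, also adjusted over the list alone: Ndufs7, by 1.90 ± 0.44.

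By size of change, the genes highest in arch against thymus also included Sik1, a kinase gene induced by cAMP (7.39 ± 0.66), Sgip1 (1 thymus read; ratio 7250, 95% interval 1300 to 286000), Gem (no thymus read, at least 808-fold), Snx18 (6.65 ± 0.65) and Nr4a2 (6.63 ± 1.33). Those lowest were the noncoding RNA Nron (-5.48 ± 1.15), the Janus kinase gene Tyk2 (-5.24 ± 0.92), the zinc transporter gene Slc39a6 (-5.05 ± 0.95) and Gpr180 (-4.99 ± 0.89). They were followed by Art1 (-4.74 ± 1.00), Pgpep1 (-4.59 ± 1.11), Myo1f (no arch read, at least 127-fold lower) and Stx4a (-4.45 ± 1.03). Crem, a cAMP-responsive transcription factor gene chosen after its values were seen, had the smallest p in the table (5.84 ± 0.31; adjusted p = 1.65e-09). Of the tested genes, 13.2% had pool values that did not overlap between arch and thymus, against 2.86% by chance. With edgeR's quasi-likelihood test on recovered reads 380 genes were called (283 higher, 97 lower), with DESeq2 1270, and without the 3 shallow columns 318 (229 higher, 89 lower). In edgeR Nr4a2, Slc39a6, Art1, Pgpep1, Stx4a, Hes1, Cdkn1a and Trp53inp1 did not pass (adjusted p 0.0687 to 0.352), nor did Nr4a2 (0.195) and Hes1 (0.151) in DESeq2, and of 8 fits without 1 pool the call was kept in 7 for Pgpep1 (0.0527 without thymus pool 1) and in 2 for Trp53inp1 (up to 0.0921, without thymus pool 3).

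DP sorts from mediastinal adipose tissue also had higher immediate early and heat shock transcripts and lower thymocyte transcripts than DP sorts from thymus. Of 9106 genes 259 were called, 198 higher and 61 lower in adipose tissue. Fosl2 went from 3 reads in thymus to 17965 in adipose tissue (ratio of means 7820, 95% interval 2680 to 37900). Selplg, whose product binds P-selectin (chromosome 5, 113817798 to 113832528), rose from a normalised count of 15030 ± 2420 to 67540 ± 14800 (SD, n = 4), a log2 change of 2.15 ± 0.22. Cd8b1 fell by 1.62 ± 0.23, from 89670 ± 15100 to 30740 ± 12500, and Ptcra (chromosome 17, 46755663 to 46763712) fell by 2.51 ± 0.50.

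Of 30 thymocyte identity genes 12 fell, 1 rose and 17 did not pass in adipose tissue; adjusted over the list alone, 21 fell and 1 rose. The median was -1.0 (camera adjusted p = 1.33e-12; adjusted p = 0.0538 with an estimated correlation). Satb1 fell by 1.17 ± 0.14, Tespa1, a gene of receptor signalling in thymocytes, by 1.98 ± 0.26, Cd8a by 1.18 ± 0.23 and Dntt by 1.22 ± 0.20. Rag1 fell by 1.53 ± 0.34. Cd4 (-0.68 ± 0.28, adjusted p = 0.27) and Rag2 (-1.90 ± 0.60, adjusted p = 0.117) did not pass, and Cd24a rose by 1.96 ± 0.23. The 4 CD3 genes did not pass (median -0.30). The list's medians in adipose pools 1 to 4 were -0.97, -0.82, -1.05 and -0.95; pool 1 was the one with raised B cell, adipocyte and fibroblast markers.

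Of 27 immediate early genes 8 rose, 1 fell and 18 did not pass in adipose tissue (10 and 1 adjusted over the list alone), with a median of 2.05 (camera adjusted p = 1.26e-07; adjusted p = 0.116 with an estimated correlation). Dusp1 rose by 3.33 ± 0.34, Dusp5 by 3.40 ± 0.58 and Junb by 3.19 ± 0.43. Egr1, a zinc finger factor gene, was the member that fell by 3.51 ± 0.81. Of 18 heat shock genes 6 rose and 0 fell (11 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 3.87e-08; adjusted p = 0.141 with an estimated correlation). Hsph1 rose by 3.49 ± 0.42, Hspe1 by 2.15 ± 0.40 and Hsp90aa1 by 2.00 ± 0.30, and Hspa1a (no thymus read) was at least 551-fold higher. Heat shock medians in adipose pools 1 to 4 were 1.40, 0.52, 1.58 and 0.89 above the thymus mean, and immediate early medians 2.56, 0.55, 1.36 and 1.02. Markers of other cells, without the most abundant of each list, summed to 2242 CPM in pool 1, where the immediate early median was highest, and to 145.7 to 251.1 CPM in the other adipose pools.

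Lists with fewer called members in adipose tissue against thymus were led by the unfolded protein and integrated stress responses, of which 3 of 22 rose and 0 fell, 4 when adjusted over the list alone. Their median was 0.65 (camera adjusted p = 0.000536, adjusted p = 0.079 with an estimated correlation), with Hspa5 at 1.43 ± 0.29. Of 19 oxidative stress genes 2 rose and 0 fell, 4 when adjusted over the list alone (median 0.44, camera adjusted p = 0.036, adjusted p = 0.296 with an estimated correlation), and Prdx6, a peroxiredoxin gene, was at 2.24 ± 0.19. Of 23 cholesterol biosynthesis genes 1 rose and 0 fell, 5 when adjusted over the list alone (median 0.55, camera adjusted p = 0.0353, adjusted p = 0.202 with an estimated correlation), namely Insig1 by 2.72 ± 0.54. S phase genes were higher as a list, with 0 of 39 called by limma, also adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2 (median 0.41, camera adjusted p = 0.028, adjusted p = 0.479 with an estimated correlation). Oxidative phosphorylation genes were lower as a list, with 0 of 75 called by limma, also adjusted over the list alone, 3 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2 (median -0.20, camera adjusted p = 0.0339, adjusted p = 0.634 with an estimated correlation). Leaving out 1 pool ended the oxidative stress call in 4 of 8 fits (up to 0.0808, without thymus pool 1) and the cholesterol, S phase and oxidative phosphorylation calls in 3 of 8 each (up to 0.0996 without adipose pool 4, 0.123 without adipose pool 3 and 0.304 without adipose pool 1). These 4 calls were also lost without the member of largest t (0.0551 to 0.158).

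Lists that did not pass camera in adipose tissue against thymus held single called genes. Among 24 p53 and apoptosis genes (camera adjusted p = 0.204, median 0.02, mean 0.79) 2 rose and 1 fell, also adjusted over the list alone, with Bcl2l11 at 4.09 ± 0.40, Cdkn1a at 5.01 ± 1.00 and Trp53inp1 at -1.65 ± 0.33. Among 16 glucocorticoid response genes (0.0763, but a fry adjusted p of 0.00175; median -0.05, mean 0.61) 3 rose, 4 when adjusted over the list alone, with Tsc22d3 at 1.61 ± 0.26 and Rgs2 at 2.58 ± 0.39. Of 29 fatty acid genes (0.538) 2 rose and 1 fell, 3 and 1 when adjusted over the list alone. Acsl3, an acyl-CoA synthetase gene, rose by 3.57 ± 0.40 and Plin2 by 2.15 ± 0.40. Selplg was the called member of 23 trafficking genes (0.665, median -0.28, mean 0.19), of which 1 was higher and 3 lower when adjusted over the list alone. Tnfaip3 rose by 2.06 ± 0.32 among 17 NF-kB targets (0.332) and Ctla4, an inhibitory receptor gene, by 5.44 ± 0.91 among 16 effector and memory genes (0.703, median -0.15, mean 0.48), each as the called member, also adjusted over the list alone. Of 21 post-selection genes (0.733) 1 rose and 1 fell, 3 and 3 when adjusted over the list alone.

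By limma no member passed in adipose tissue against thymus, also adjusted over the list alone, among early double-negative thymocyte (camera adjusted p = 0.577), type I interferon (0.0688, median -0.67) and hypoxia and glycolysis genes (0.594). The same was found for G2 and M phase genes (0.666, median 0.01, mean -0.15) and ribosomal protein genes (0.615, median 0.06). At an unadjusted p under 0.05 these 5 lists had 2, 2, 3, 5 and 2 members. edgeR called 0 in each, and DESeq2 called 2 hypoxia and glycolysis and 2 ribosomal protein genes.

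By size of change, the genes highest in adipose tissue against thymus also included Sik1 (6.50 ± 0.66), Snx18 (6.39 ± 0.65), Sgip1 (1 thymus read; ratio 5310, 95% interval 952 to 210000), Tex2 (6.35 ± 0.70), Per1 (6.19 ± 0.74) and Spsb1 (5.86 ± 0.86). Crem, again singled out after its values were seen, was at 5.03 ± 0.31. Besides Egr1 and Ptcra, the lowest were Gtpbp8 and Tmprss4 (no adipose read, at least 110-fold and 78.7-fold lower), the meiotic endonuclease gene Spo11 (-2.45 ± 0.55), Stambpl1 (-2.39 ± 0.63), Tdrd5 (-2.28 ± 0.45) and P2rx1, an ATP receptor gene (-2.11 ± 0.55). Pool values did not overlap for 10.5% of the tested genes, against 2.86% by chance. DESeq2 called 710 genes and edgeR 208, in which Spsb1, Gtpbp8, Egr1, Tmprss4, Stambpl1, P2rx1, Ctla4, Cdkn1a and Rag1 did not pass (adjusted p 0.0513 to 0.2; Stambpl1 not in DESeq2 either, at 0.0507), and without adipose pool 4 there were 169 calls. Of 8 fits without 1 pool, the call was kept in 5 for Rag1 (adjusted p up to 0.0628, without adipose pool 3), 4 for Egr1 (up to 0.0816, without thymus pool 1) and 3 for Spo11 (up to 0.0761, without thymus pool 2). It was kept in 1 for Stambpl1 and 0 for P2rx1 (up to 0.122 and 0.138, without adipose pool 1). Gtpbp8 and Tmprss4 kept it in 1 of the 4 such fits that tested them (up to 0.0694 and 0.0716, without adipose pool 4).

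The comparisons of arch and adipose tissue with thymus shared 208 called genes with the same direction (165 higher, 43 lower) and 0 with opposite directions in limma. Fosl2, Sik1, Per1, Hsph1, Cd24a and Bcl2l11 were among those higher in both, and Satb1, Cd8b1, Cd8a and Dntt among those lower in both. Independent lists of these lengths would share 7.89 higher and 1.57 lower genes. In 20 simulations with no effect but the same thymus pools 0 were shared, a count that is no yardstick for the 208, because nearly no gene is called where nothing differs. With 2 thymus pools set against arch and the other 2 against adipose tissue, so that no control was shared, 94 to 105 genes were shared over 6 arrangements. Log2 changes correlated across genes at 0.682 (0.499 in the simulations; 0.338 to 0.404 with split controls), with a covariance of 1.09 against 0.397 simulated, a difference of 0.694. These are correlations across genes, which are not independent replicates.

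Heat shock genes set arch DP sorts apart from adipose DP sorts. Of 16 genes called, 9 were higher and 7 lower in arch, and 8 of the 9 encode heat shock proteins or their cochaperones. Hspe1, the cochaperonin of mitochondria (chromosome 1, 55088148 to 55091317), rose by 3.22 ± 0.40, from a normalised count of 8274 ± 5520 in adipose tissue to 70360 ± 28700 in arch (SD, n = 4). Hsp90aa1 rose by 2.44 ± 0.30, Hsph1 by 2.31 ± 0.42, Hspd1 by 2.21 ± 0.35, Hspa8 by 1.79 ± 0.32, Hsp90ab1 by 1.67 ± 0.31, Dnaja1 by 1.66 ± 0.31 and Dnajb1 by 1.32 ± 0.22. The other gene higher in arch was Id3, an inhibitor of E protein transcription factors, at 1.87 ± 0.29. Of 18 tested heat shock genes, limma called 8, edgeR 3 and DESeq2 9. Without a filter limma did not call Hsph1, Hspd1, Hspa8, Hsp90ab1, Dnaja1, Dnajb1 or Id3 (adjusted p 0.0582 to 0.193).

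As a list, 8 of 18 heat shock genes rose in arch against adipose tissue and 0 fell, 13 when adjusted over the list alone (median 1.49, camera adjusted p = 2.38e-16, adjusted p = 0.0538 with an estimated correlation). Immediate early genes were higher as a list, with 0 of 27 called by limma, 1 when adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2 (median 0.76, camera adjusted p = 0.000168, adjusted p = 0.21 with an estimated correlation). So were ribosomal protein genes, with 0 of 76 called by limma, also adjusted over the list alone, 34 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2 (median 0.42, camera adjusted p = 2.1e-15, adjusted p = 0.338 with an estimated correlation). Thymocyte identity genes did not pass (camera adjusted p = 0.654), with 0 of 30 called by limma (6 at an unadjusted p under 0.05, 0 by edgeR, 2 by DESeq2), 1 higher when adjusted over the list alone and a median of -0.09 against an upward camera direction. Cd8a was at 0.10 ± 0.23, Cd8b1 at 0.16 ± 0.23, Dntt at 0.03 ± 0.20 and Cd4 at -0.61 ± 0.28.

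Genes lower in arch than in adipose tissue were Gpr180 (-5.11 ± 0.89), the DNA glycosylase gene Neil1 (-2.30 ± 0.45), Dgat1, an enzyme gene of triglyceride synthesis (-2.14 ± 0.37), and the T-cell kinase gene Txk (-1.57 ± 0.28). Ndrg3 fell by 1.31 ± 0.24 and Selplg by 1.17 ± 0.22. Selplg was the called member of the trafficking list (1 of 23 fell, camera adjusted p = 0.351), of which 1 was higher and 2 lower when adjusted over the list alone. In edgeR 9 of the named genes did not pass (adjusted p 0.0522 to 0.234). They were the heat shock genes Hsph1, Hspd1, Hspa8, Hsp90ab1 and Dnaja1, and Neil1, Dgat1, Txk and Selplg.

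The remaining lists did not pass in arch against adipose tissue, and limma called none of their members, with 0 to 6 per list at an unadjusted p under 0.05, 0 by edgeR and 0 to 3 by DESeq2. Medians were 0.47 for early double-negative thymocyte, -0.59 for post-selection, 0.17 for effector and memory and 0.37 for p53 and apoptosis genes. They were 0.42 for glucocorticoid response (2 higher and 2 lower adjusted over the list alone), 0.26 for unfolded protein response, -0.01 for oxidative stress (2 higher adjusted over the list alone) and 0.29 for cholesterol biosynthesis genes. For NF-kB targets, type I interferon, hypoxia, fatty acid, S phase, G2 and M phase and oxidative phosphorylation genes they lay between -0.37 and 0.04, and the 4 CD3 genes had a median of -0.08. Camera adjusted p over these lists ranged from 0.0703 to 0.929. The camera direction was upward for oxidative stress, NF-kB, interferon and hypoxia genes in spite of medians just below 0.

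Over all genes of arch against adipose tissue, 954 had an unadjusted p under 0.05 and 5.35% had pool values that did not overlap, against 2.86% by chance. The count of calls was 6 with edgeR on recovered reads and 289 with DESeq2, and 0 by limma without the 3 shallow columns (611 at an unadjusted p under 0.05) or without arch pools 2 and 4 (513). Leaving out 1 pool left 2 to 14 calls, with 5, 9 and 2 without adipose pools 2, 3 and 4 and 3 and 5 without arch pools 2 and 4. Hspe1 and Hsp90aa1 were called in all 8 such fits. The other named genes kept their calls in 1 to 6 of the 8, with adjusted p up to 0.28 for Neil1 without adipose pool 4. Arch pools 2 and 4 also held the raised fibroblast (7015 CPM in pool 4), smooth muscle (1977 CPM in pool 2) and macrophage markers (2349 CPM in pool 2).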

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

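The 4 tests on heat shock and immediate early genes, the test of dilution and the fits without shallow columns or without arch pools 2 and 4 were chosen only after the data were seen; the counts over splits of the pools were planned.

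Heat shock and immediate early genes were higher in arch than in thymus in all 4 arch pools, and the authors' scaling was argued against, since the tested members lay 2.63 (log2) above the median of all tested genes. As a sum, cells of the 13 other listed types were argued against as the whole cause for heat shock genes. The lowest arch pool median lay 2.08 (log2) above the thymus mean, in pool 1 with 359.6 CPM of their markers (without the most abundant of each list). The median was 2.37 in pool 4 with 5620 CPM. For immediate early genes these cells cannot be told apart from a change in DP cells, because the medians were higher where the markers were, at 2.81 and 2.82 in arch pools 2 and 4 against 2.27 and 1.09 in pools 1 and 3, and the lowest had a standard error of 0.648 over members. Enzymatic digestion, which the labels state for arch and adipose tissue and not for thymus, cannot be told apart from the tissue for these genes, because no thymus stated to be digested was measured; arch exceeded adipose tissue by a heat shock median of 1.49. The marker sum cannot decide on NK and innate lymphoid cells. Their markers without Gzma were above thymus in every arch pool, but that sum was led by Rora and does not show a rise of several markers. Without Gzma the NK and innate lymphoid cell markers were 20.96, 48.54, 29.08 and 20.22 CPM in arch pools 1 to 4 and 0 to 0.07422 CPM in thymus pools. Nor can the sum alone decide on fibroblasts. Without Gsn their markers were 22.69, 228.5, 8.625 and 4771 CPM in arch pools 1 to 4 and at most 3.871 CPM in thymus pools. The heat shock medians of these arch pools, 2.08, 2.26, 2.40 and 2.37, did not follow the fibroblast markers. Cells of types outside the lists and a difference of the cells between tissues stay open, untested, and the response may come from dissociation, from the tissue or from both.

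Thymocyte identity genes were lower in arch than in thymus, with a list median of -0.99. Dilution by RNA of cells that transcribe none of the list's genes would lower all members alike. Yet 10 of 30 members had a 95% interval that excludes the list's median (5 above, 5 below, against 1.5 by chance), and Cd24a rose. That argues against such dilution as the whole cause. The test cannot decide on cells that transcribe some members, because these would lower members unequally or raise some. Shallow libraries were argued against too, because without arch pools 2 and 4 and thymus pool 3 the median was -0.945. A difference in developmental stage or in the cells that pass the gate could underlie the pattern and stays open, untested.

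Of the genes called against thymus, 39.3% were lower in arch and 23.6% in adipose tissue. Shallow libraries in arch pools 2 and 4 may contribute, since a gene missed in a shallow library reads as lower. Without these pools 32.6% of the called genes were lower in arch. That lay between the bounds for and against this explanation (25 and 35), which were set before this fit was run. By that fit depth and tissue cannot be told apart for this share. Leaving out these pools also removed those with raised fibroblast, smooth muscle and macrophage markers, so it does not single out depth. Reads thinned to equal depth gave similar counts of calls, but the share of lower genes among them is not given here. The contrast itself depended on the test: the share of higher genes in arch and adipose tissue was 60.7% and 76.4% with limma, 74.5% and 78.8% with edgeR and 69.9% and 63.8%, the other way round, with weighted voom. Without the 3 shallow columns it was 72% and 71.8%.

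For the counts of called genes, 1 of 35 splits of the 8 pools, the real one, called as many in each comparison. An exact p of 0.0286 is the smallest that 35 splits can give, and it was not adjusted over comparisons. The splits thus argue against chance for these counts but cannot exclude it. The real counts were 598, 259 and 16 for arch against thymus, adipose tissue against thymus and arch against adipose tissue, and the highest of the other splits were 0, 2 and 1. For the number of called lists in adipose tissue against thymus, 1 of 35 splits gave as many (8, highest other 7). The margin over the other splits was narrow, and these list calls did not hold with an estimated correlation. In arch against thymus 2 of 35 gave as many (9, highest other 9), and in arch against adipose tissue 22 of 35 did (3, highest other 7). Chance cannot be excluded for the number of called lists.

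Of 300 groups of 4 pools, 30 (10%) held a pool whose gap to the others took an unusual share of the group's range. Chance alone gives about 1 in 20 for normally distributed values, which many of these groups were not. Marker sums were screened without logarithms. Where the other pools held 0, 1 read was enough to flag a pool, as for Hmox1 and Sgip1 in thymus. The share of flagged groups is therefore no evidence that pools were more uneven than chance allows. Genes were screened as log2(normalised read count + 20), which gave 20 of 249 groups (21 without logarithms), and library and marker measures gave 10 of 51. Among marker sums, adipose pool 1 stood apart for B cell markers (1815 CPM, others 32.87 to 183.1), adipocyte (223.3, others 0 to 15.55), fibroblast (532.1, others 59.28 to 136.2), neutrophil (23.49, others 7.876 to 9.449) and cardiomyocyte markers (12.25, others 0). Arch pool 4 stood apart for fibroblast markers (7015 CPM, others 132.1 to 359.7) and arch pool 2 for smooth muscle (1977, others 0.6997 to 78.64) and neutrophil markers (74.97, others 11.65 to 19.24). Thymus pool 3 was low for NK and innate lymphoid markers (83.87 CPM, others 94.19 to 95.09), and adipose pool 3 held 0.03351 CPM of mesothelium markers where the others held 0.

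Among named genes with low thymus counts, thymus pool 1 stood apart for Fosl2 (1.698, others 0), Per1 (35.1, others 0 to 0.8249), Nr4a2 (546.2, others 0) and Hmox1 (0.5661, others 0), all as normalised read counts. It was lower than the other thymus pools for Art1 (574.0, others 780.9 to 824.1). Thymus pool 3 stood apart for Sgip1 (1.457, others 0) and Crem (662.7, others 411.6 to 445.8), thymus pool 4 for Cdkn1a (125.4, others 0 to 0.5661), Cd4 (22770, others 16360 to 16600) and Prdx6 (4927, others 7927 to 8645), and thymus pool 2 for Hspa5 (2824, others 4789 to 5261). In arch pool 3 transcripts that were at or near 0 in the other arch pools were present, namely Slc39a6 (377.1, others 0 to 3.257), Art1 (62.99, others 0), Pgpep1 (44.42, others 0 to 3.804) and Stx4a (146.2, others 0). Arch pool 1 held 42.35 of Gtpbp8 (others 0) and arch pool 2 held 47580 of Crem (others 23030 to 24990). In adipose tissue, pool 1 was high for Gem (1525, others 342.1 to 413.9), and pool 4 was high for Cd4 (19710, others 8575 to 9713) and low for Stx4a (68.13, others 520.7 to 662.2).

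The changes against thymus differed between arch and adipose tissue, by the direct test of the difference, for the heat shock list (camera adjusted p = 2.38e-16), the ribosomal protein list (2.1e-15), the immediate early list (0.000168) and 16 single genes in limma. With an estimated correlation none of these 3 lists passed (adjusted p = 0.0538, 0.338 and 0.21).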

How the results depend on the processing

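TMM scaling with limma, pseudocounts of 1 and 100 and a stricter filter were chosen only after the data were seen. So were the fits without shallow columns or arch pools 2 and 4. edgeR with TMM was the test planned for the 3 comparisons and was run with the filter of the main test. The cause of the shifts below was not tested unless stated. No gene was called in the opposite direction in the alternatives for counts of genes. Of 1517 alternatives for 304 named-gene results, 1357 kept their side of the threshold, 119 lost the call, 41 gained it and 0 reversed; DESeq2 gave no adjusted p for 3 more. Of 140 alternatives for 20 single lists 100 kept the call and 40 lost it. The adjusted exact tests of library measures and marker sums have almost no room to pass under any alternative, so their unchanged calls say nothing about stability.

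The 598, 259 and 16 calls (arch against thymus, adipose tissue against thymus, arch against adipose tissue) became 380, 208 and 6 with edgeR. With edgeR and TMM, the test planned at first, they became 365, 212 and 8 (76.2% higher in arch against thymus). DESeq2 gave 1270, 710 and 289 calls, and weighted voom 512, 426 and 24 (63.8% higher in adipose tissue against thymus). At an adjusted p under 0.01 in the main test, a stricter threshold by construction, the calls were 267, 148 and 2. Arch against adipose tissue gave 2 without a filter and 9 with a pseudocount of 1. Without the 3 shallow columns there were 318, 319 and 0 calls (72% higher in the first), and without arch pools 2 and 4 there were 334 in arch against thymus and 0 in arch against adipose tissue, where fewer pools were compared and 611 and 513 genes had an unadjusted p under 0.05. Without 1 pool each, counts ranged from 405 to 623, from 169 to 247 and from 2 to 14. Reads thinned to equal depth gave 595, 262 and 16, and the remaining alternatives stayed within 1.5 times.

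The overlap of 208 became 547 with DESeq2, 122 at an adjusted p under 0.01, 99 with split thymus pools (median) and 147 to 228 without 1 pool. The 9, 8 and 3 called lists became 0, 0 and 0 with an estimated correlation, 9, 6 and 1 with fry, 6, 4 and 3 without the member of largest t, and 10, 7 and 5 both without shallow columns and without arch pools 2 and 4. Without 1 pool they ranged from 7 to 11, 5 to 10 and 3 to 5. The separation of arch from adipose pools ranged from -0.00423 (without adipose pool 4; -0.00012 without adipose pool 2) to 0.0347, that of arch from thymus from 0.0642 to 0.0926 and that of adipose tissue from thymus from 0.0438 to 0.0561.

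With the pool number as a replicate block 608, 243 and 12 genes and 9, 8 and 4 lists were called; Ndrg3 and Selplg (adjusted p = 0.0745 each) and Neil1 (0.0789) were not called in arch against adipose tissue, nor P2rx1 (0.0768), Dnajb9 (0.0563) and Ucp2 (0.062) in adipose tissue against thymus. Same-numbered pools deviated together little (correlations -0.0316 to 0.0756, 0 over 0.1), and 5 of 12 columns correlated best with their own number. The labels do not state whether a number marks the same mice in all tissues, and the pools were not treated as paired. Values per library were not analysed here, so each library as its own sample, a correlation between libraries, the first library of each pool alone, a mean over libraries and the mitochondrial share could not be run. The depth and 4 pools leave 2-fold changes mostly undetected (1.59%, 0% and 3.17% recovered in simulation).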

Other observations

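The list of cAMP-responsive genes below was tested only after Crem, Sik1 and Per1 had been seen to be high, with its members fixed before their own values were looked at; the comparison of medians between relabelled pools was also added later.

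Crem, which encodes a cAMP-responsive transcription factor, averaged 485.8 normalised reads in thymus, 17080 in adipose tissue and 29770 in arch, and it had the smallest p of all genes in both comparisons with thymus. Sik1 and Per1, which are known targets of cAMP signalling, were among the genes with the largest rise in both tissues. A hypothesis is that DP cells outside the thymus carry a cAMP response. A separate list of 9 genes known to respond to cAMP had 6 tested members with a median log2 change of 1.45 in arch against thymus (camera p = 6.94e-05, p = 0.00294 with an estimated correlation). Of these 6, Cited2 (2.04 ± 0.58), Pde4b (1.45 ± 0.27) and Tob1 (2.28 ± 0.58) rose. In adipose tissue against thymus the median was 1.59 (camera p = 0.000575, p = 0.00678 with an estimated correlation), with Pde4b called at 1.41 ± 0.27 and 4 members called when adjusted over the list alone. The camera p of this later list were not adjusted, so they cannot be set beside the adjusted p of the other lists. In arch against thymus the unadjusted p with an estimated correlation was 0.00199 for heat shock and 0.00445 for unfolded protein response genes. It was 0.00524 for immediate early and 0.00538 for thymocyte identity genes, and each became 0.0538 after adjustment. Between arch and adipose tissue the median of the cAMP list was 0.31, with an unadjusted camera p of 0.138 in limma. The test could have gone the other way and is in line with the hypothesis, but many of these genes also respond to other stimuli, digestion included, so a cAMP response remains a candidate explanation only.

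When the pools were relabelled in all 35 ways, the medians of some lists were matched by other splits. In arch against thymus the real split gave the largest absolute median for the thymocyte identity, immediate early, heat shock, unfolded protein response and cholesterol lists (exact p = 0.0286 each), but not for ribosomal protein, oxidative stress and glucocorticoid genes (0.0571 each) or p53 genes (0.0857). In adipose tissue against thymus it did so for the identity, immediate early, heat shock, unfolded protein response and oxidative stress lists (exact p = 0.0286 each), with 0.114 for cholesterol and S phase genes and 0.2 for oxidative phosphorylation genes. In arch against adipose tissue heat shock genes gave an exact p of 0.0286, and immediate early and ribosomal protein genes 0.0857. Of the lists that did not pass camera, type I interferon genes in arch against thymus (-1.25) and unfolded protein response genes in arch against adipose tissue (0.26) also had their largest absolute median under the real split (exact p = 0.0286 each).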
